A study of Mus musculus with 9 samples.

How the data were processed

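RNA sequencing was done on 9 libraries from the mouse pancreatic ductal adenocarcinoma line 908, which was established from tumors of mice with pancreas-specific Cre, a mutant Kras allele and 1 floxed Tsc1 allele. The labels assign 3 libraries to cells carrying a control open reading frame and selected with geneticin, 3 to cells with high Aldh1a3 overexpression and 3 to cells with low Aldh1a3 overexpression, both of the latter after monoclonal selection. Cells were grown in DMEM with fetal bovine serum. Per the labels, RNA was either enriched for mRNA or depleted of ribosomal RNA, without stating which, then primed with random hexamers and circularised for sequencing. The genotype labels of the low libraries 2 and 3 name Aldh1a4 and Aldh1a5, while their treatment labels name Aldh1a3; all 3 were kept in the low group. The labels do not say whether the 3 libraries of a group are separate cultures or technical repeats, so n counts libraries and not independently derived lines.

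The authors deposited 1 table per library with values in FPKM (fragments per kilobase of transcript, scaled to the mapped reads of the library), rounded to 2 decimals; the genome build is mm10, and the aligner, the counting tool and their versions are not given in the sources used here. Each table has 22261 entries, of which 20716 carry an Entrez number, 1543 an identifier of an unannotated locus and 2 name no gene. Values are given for 17929 entries, the same in every table, and 17928 of them carry a usable identifier. Symbols and positions were joined by Entrez number and found for 16466 of these. Neither read counts nor depths are given. The spacing of the smallest values gave a step of 0.0198 to 0.0220 FPKM times kilobase in the 9 libraries at an assumed fragment length of 150 bases. If 1 step is 1 fragment, this is 4.55e+07 to 5.05e+07 fragments per library, and 3.66e+07 to 6.41e+07 over assumed lengths of 0 to 300 bases. The spacing was imperfect (mean cosine 0.187 to 0.572, where 1 is exact), so fragments per gene were not recovered and no counting intervals are given.

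Genes with at least 1 FPKM in at least 3 of the 9 libraries were kept, which left 11287 genes, 10806 of them with a symbol. Values were analysed as log2(FPKM + 1) without further scaling with limma 3.58.1 in R 4.3.3. A single model with 3 group means was fitted to all 9 libraries, with moderated variances that follow a trend in intensity and 6 residual degrees of freedom. Log2 folds are differences of group means on this scale, which understates the fold of genes near or below 1 FPKM. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes kept. Verbs of change below refer to such calls. Where a single gene was also tested alone, an exact two-sided permutation test of the means was used, whose smallest possible p with 3 against 3 libraries is 0.1. An F test over the 3 group means counted genes that differed in any group.

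Gene lists, tests, the rule for named genes and most alternatives were fixed before the data were examined. Of 45 lists of pathway genes and cell type markers, 40 had at least 5 tested members and were tested in each comparison with limma's camera at an inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and the rotation test fry were run beside it, and members were also counted after a Benjamini-Hochberg correction of their p, adjusted over the list alone. On simulated data with no group difference, camera at 0.01 called on average 13.05, 13.15 and 13.6 of the lists in high against control, low against control and high against low, and 0 with an estimated correlation. A shift of 0.5 planted in a list was found in 20, 20 and 18 of 20 draws at 0.01, and in 7, 7 and 8 with an estimated correlation. The counts of changed members therefore carry the description of each list. These counts come from the same correlated genes and were not checked on simulated data. Each simulated library took a random mixture of the observed deviations. In the real design each group holds 1 library of each number, and libraries of the same number share deviations. The simulation does not keep this balance, so the rates in the real design may differ. Of all tested genes, 14.98%, 11.99% and 15.81% were called in the 3 comparisons, and counts near these shares do not set a list apart. The single-gene test, checked on the same simulated data with 200 changed genes per draw, recovered 86.8%, 85.3% and 85.4% of log2 folds of 1 and 52.5%, 48.7% and 50.6% of folds of 0.5 in the 3 comparisons, with a false share of 0.1%, 0.9% and 2.9%. Chromosomes were tested as gene sets by camera with an estimated correlation.

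Named genes are Aldh1a3, the 4 genes in the title of the series (Sema4d, Plxnb1, Sema3a and Nrp1), the 10 rising and 10 falling genes with the largest absolute log2 fold in each comparison with control (5 and 5 between the overexpressing lines), and up to 4 members of each list. The genes of largest fold had a mean of at least 5 FPKM in the higher group, no overlap between the groups compared and no predicted or clone-based name; list members had at least 1 FPKM in either group. Among these, the text prefers genes that kept their call when each library was left out in turn. The libraries of different groups that carry the same number were checked for shared deviations from their group means: these correlated above 0.1 in all 3 numbers for control with low and for high with low, but not for control with high. A model with the number as a block was therefore run beside the plain one. It called 3384, 2590 and 3643 of the 11287 tested genes in the 3 comparisons. List counts given with the block are to be read against these larger shares, and counts near or under them do not set a list apart.

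The alternatives were other pseudocounts (0.1 and 0.01), no filter and a filter at 5 FPKM, quantile normalization and median-ratio scaling, moderation without trend or robust, weights per library, fits of only the groups compared, the block, a minimum absolute log2 fold of 1, both other list tests and each library left out in turn. Camera with an estimated correlation together with the block, leaving out the 3 libraries numbered 3, leaving out the genes on chromosomes 3, 14, 18 and Y, and all alternatives of the chromosome test were added after the data were seen. The 2 entries that name no gene and the entries without values were left out. Mitochondrial transcripts could not be described because none of the 13 on the list is in the tables. Figures were drawn with matplotlib 3.10.9.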

Results

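Transcript levels were measured by RNA sequencing in 9 libraries of the mouse pancreatic ductal adenocarcinoma line 908, with 3 libraries each from control cells, a line with high and a line with low Aldh1a3 overexpression. Aldh1a3 is an aldehyde dehydrogenase that oxidises retinal to retinoic acid. The deposited FPKM of a library summed to between 486394 in low 2 and 513299 in control 3, and between 10849 and 11080 genes reached 1 FPKM. The depth is not given, and the spacing of the smallest values puts it roughly at 3.66e+07 to 6.41e+07 fragments per library, depending on the assumed fragment length. Pearson correlations across genes of log2(FPKM + 1) were 0.974 to 0.997 between libraries of a group and 0.953 to 0.98 between groups. Genes are not independent replicates. Both overexpressing lines are labelled as monoclonally selected, while the control label names selection by geneticin without saying whether a clone was picked. The Aldh1a3 level, the clone and the selection therefore cannot be separated in this design. Values below are mean ± SD over n = 3 libraries per group, and log2 folds are followed by their standard error where one is given.

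The level of Aldh1a3 itself (Entrez 56847, mm10 chromosome 7, 66390892 to 66427477) followed the labels. It stood at 5.15 ± 1.19 FPKM in control, 35.6 ± 6.71 in the low line and 113 ± 13.1 in the high line. The log2 fold over control was 4.22 ± 0.17 in the high line (adjusted p = 1.97e-06) and 2.57 ± 0.17 in the low line (adjusted p = 2.94e-05). The high line exceeded the low line by 1.65 ± 0.17 (adjusted p = 0.000396). In linear terms the means were 21.9 times control in the high line and 6.91 times control in the low line. The values of the 3 groups did not overlap, and the exact two-sided permutation p was 0.1 in each comparison, the smallest that 3 against 3 libraries allow. All 3 low libraries lay between 27.9 and 39.8 FPKM, including the pair whose genotype labels name other Aldh1a genes.

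The title of the series names 2 semaphorins, secreted or membrane-bound guidance cues, and 2 of their receptors. Plxnb1 (Entrez 235611, chromosome 9, 109093849 to 109119915), the plexin that binds Sema4d, rose from 1.7 ± 0.35 FPKM in control to 5.05 ± 0.49 in the high line and 5.83 ± 0.71 in the low line. Its log2 folds were 1.17 ± 0.12 (adjusted p = 0.000227) and 1.34 ± 0.12 (adjusted p = 0.00012). Sema3a (Entrez 20346, chromosome 5, 13124822 to 13603485) fell from 44.8 ± 8.57 FPKM to 15.3 ± 0.71 in the high line and 20.1 ± 3.5 in the low line, with log2 folds of -1.47 ± 0.15 (adjusted p = 0.000325) and -1.11 ± 0.15 (adjusted p = 0.00166). Neither gene was called between the overexpressing lines (adjusted p = 0.379 for Plxnb1 and 0.173 for Sema3a). Sema4d (Entrez 20354, chromosome 13, 51685529 to 51793678) rose in the high line, from 1.27 ± 0.27 to 2.22 ± 0.29 FPKM (log2 fold 0.51 ± 0.11, adjusted p = 0.0126), and stood at 1.32 ± 0.1 in the low line (adjusted p = 0.898). The direct test of the high against the low line gave 0.47 ± 0.11 for Sema4d (adjusted p = 0.0175). Nrp1 (Entrez 18186, chromosome 8, 128358591 to 128505476), a co-receptor for Sema3a, was at 16.7 ± 1.37 FPKM in control, 20.6 ± 0.99 in the high line and 19.2 ± 1.36 in the low line. Its log2 fold of 0.29 ± 0.08 in the high line was at the threshold (adjusted p = 0.0493). In the low line the fold of Nrp1 was 0.19 ± 0.08 and was not called (adjusted p = 0.197). The Sema4d call against control was lost without high 1 (adjusted p = 0.0581) or high 2 (0.0571), and the call between the lines without high 1 (0.0766), high 2 (0.0733), low 1 (0.0649) or low 3 (0.0579). That of Nrp1 was lost without any single library except low 3, with adjusted p from 0.0503 without control 1 through 0.0718 (control 2), 0.147 (control 3), 0.138 (high 1), 0.0909 (high 2), 0.13 (high 3), 0.067 (low 1) and 0.0761 (low 2).

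**Figure D1:**
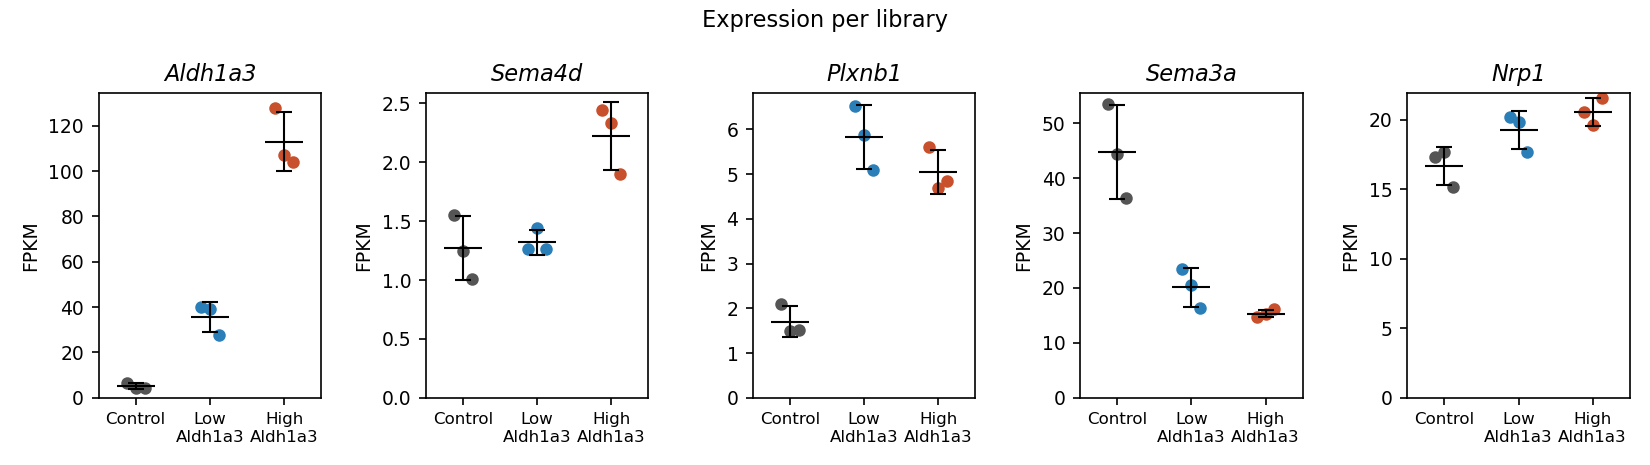
FPKM of Aldh1a3 and the 4 genes of the series title in each library (points) by group, with the mean (horizontal line) and SD (bars), n = 3 libraries per group; axes start at 0. The high line sits at 104 to 128 FPKM of Aldh1a3, and Sema3a lies lower in both overexpressing lines than in control.

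The comparison of the high line with control asks which transcripts differ in cells with the highest Aldh1a3 level. The interferon-induced transmembrane genes Ifitm1 and Ifitm3, whose products restrict virus entry, fell, Ifitm1 from 354 ± 63.4 to 0.757 ± 0.32 FPKM and Ifitm3 from 147 ± 22.2 to 1.89 ± 0.42. Fkbp10, a collagen-folding isomerase, fell from 21.6 ± 0.42 to 0.067 ± 0.025 FPKM, Cd34, a surface sialomucin, from 19.3 ± 2.21 to 0.017 ± 0.0058, and Galnt18, a glycosyltransferase, from 18.4 ± 1.57 to 0.183 ± 0.023. Cldn3, a tight junction claudin, rose from 3.83 ± 0.93 to 49 ± 7.9 FPKM, and Csn3, the gene of kappa-casein, from 5.14 ± 0.89 to 52.3 ± 12.5. Sprr1a, a cornified envelope precursor, rose from 122 ± 45.9 to 1393 ± 384 FPKM. Dclk1, a microtubule-associated kinase, rose from 1.08 ± 0.15 to 10.6 ± 0.89 FPKM. The log2 folds of these genes were -7.66 ± 0.17 for Ifitm1, -5.68 ± 0.2 for Ifitm3, 3.38 ± 0.17 for Cldn3 and 3.54 ± 0.36 for Sprr1a, and the highest adjusted p was that of Sprr1a, 0.00028. On this scale of log2(FPKM + 1), also among the largest changes, the tetraspanin Cd53, the transcription factor Foxd1, the organic anion transporter Abcc3, Kbtbd11 and Urah rose, with log2 folds from 2.24 (Urah and Abcc3) to 2.44 (Cd53). The neuronal pentraxin Nptx1, the microtubule regulator Stmn2 and the transcription factor Foxf1 fell by 3.51, 3.71 and 3.39. Sprr1a, Dclk1, Cd53 and Stmn2 lie on chromosome 3, whose genes as a whole had a median log2 fold of 0.24 in the high line.

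Genes of retinoid metabolism and retinoic acid response went both ways in the high line. Cyp26b1, which degrades retinoic acid and is a known retinoic acid target, rose from 2.76 ± 0.36 to 13.4 ± 2.93 FPKM, Rarb, a retinoic acid receptor on chromosome 14, from 1.71 ± 0.32 to 4.66 ± 0.59, and Aldh1a1, another retinal-oxidising enzyme, from 0.263 ± 0.16 to 2.66 ± 0.78. The retinoic acid-binding proteins Crabp1 and, on chromosome 3, Crabp2 fell, from 20.8 ± 11.5 to 0.15 ± 0.062 and from 5.45 ± 1.39 to 1.4 ± 0.55 FPKM. Of 13 tested genes of retinoid metabolism 4 rose, 4 fell and 5 did not pass, and adjusted over the list alone 6 rose and 5 fell (camera adjusted p = 0.962; adjusted p = 0.965 with an estimated correlation). Among 16 tested receptors and targets 4 rose, 1 fell and 11 did not pass, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.189; adjusted p = 0.953 with an estimated correlation). Other aldehyde dehydrogenases included 2 that rose and 4 that fell of 15 tested, or 4 and 4 adjusted over the list alone (camera adjusted p = 0.879; adjusted p = 0.965 with an estimated correlation). Aldh3a1 fell from 63.5 ± 10.5 to 21.3 ± 3.92 FPKM and Aldh1l1 from 6.78 ± 0.82 to 2.1 ± 0.84. In the semaphorin list 3 of 14 tested rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.763; adjusted p = 0.965 with an estimated correlation). Sema3e rose from 1.69 ± 0.21 to 3.7 ± 0.37 FPKM. Across the groups, 8 of the 14 semaphorins, 6 of the 16 receptors and targets and 4 of the 9 plexins and neuropilins were lower, and 0 of any of these higher, in the libraries numbered 3 than in those numbered 1. Of all 11287 tested genes, 2592 were higher and 2092 lower in number 3. Here and below, counts near these shares do not set a list apart. Of 9 plexins and neuropilins 3 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.424; adjusted p = 0.953 with an estimated correlation). Plxnd1 rose from 5.07 ± 1.17 to 10.7 ± 1.69 and Nrp2 fell from 40.1 ± 4.67 to 28 ± 2.03 FPKM.

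Mesenchymal genes, mostly matrix components and their receptors, fell more often than they rose in the high line. Of 25 tested, 11 fell, 1 rose and 13 did not pass, and 14 fell and 1 rose adjusted over the list alone, with a median log2 fold of -0.52. The collagen gene Col3a1 fell from 34.6 ± 23.2 to 0.147 ± 0.084 FPKM, the matricellular gene Sparc from 114 ± 31 to 21.2 ± 3.36, the fibrillin gene Fbn1 from 8.37 ± 0.05 to 1.61 ± 0.32 and the receptor gene Pdgfrb from 5.89 ± 2.57 to 0.477 ± 0.19. Camera gave an adjusted p = 6.44e-06 for the list, and adjusted p = 0.953 with an estimated correlation. Of the same 25 genes, 15 were lower and 0 higher in the libraries numbered 3 than in those numbered 1 across the groups. Of 4 tested fibroblast markers, of which Col3a1, Pdgfrb and Acta2 are also on this list, 2 fell and 0 rose, or 3 and 0 adjusted over the list alone, with a median of -1.78. They were too few for camera. In the list of matrix remodelling 9 of 32 tested fell and 2 rose, 10 and 2 adjusted over the list alone. Of these 32 genes 15 were lower and 2 higher in the libraries numbered 3 than in those numbered 1. Adam19 fell from 5.5 ± 0.83 to 0.31 ± 0.017, the lysyl oxidase gene Loxl3 from 11.2 ± 3.5 to 1.92 ± 0.23 and the protease inhibitor Timp3 from 43.8 ± 8.12 to 16 ± 0.7 FPKM. Its camera adjusted p = 0.00754 became 0.102 without control 1, 0.263 with the filter at 5 FPKM and 0.108 with weights per library, and adjusted p = 0.953 with an estimated correlation.

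Ductal markers rose more often than they fell. Of 11 tested, 6 rose, 1 fell and 4 did not pass, with the same counts adjusted over the list alone and a median of 0.55. Slc4a4, a bicarbonate cotransporter, rose from 2.68 ± 0.71 to 12.4 ± 2.4 FPKM, Bicc1 from 1.11 ± 0.27 to 3.9 ± 0.58, and Car2, a carbonic anhydrase gene on chromosome 3, from 3.13 ± 0.55 to 10.1 ± 2.1, while the transcription factor gene Sox9 fell from 15.5 ± 1.69 to 8.37 ± 0.94. Camera gave adjusted p = 0.0173 for the list, and adjusted p = 0.668 with an estimated correlation. Epithelial genes split, with 5 rising and 4 falling of 16 tested, or 5 and 5 adjusted over the list alone (camera adjusted p = 0.962; adjusted p = 0.965 with an estimated correlation). Beside Cldn3, the transcription factor gene Elf3 rose from 1.14 ± 0.11 to 4.29 ± 0.45 FPKM, whereas Cdh1, the gene of E-cadherin, fell from 3.24 ± 0.52 to 0.743 ± 0.068. Cytosolic ribosomal protein genes fell more often than they rose: 17 of 74 fell, 0 rose and 57 did not pass, or 30 fell and 1 rose adjusted over the list alone, with a median of -0.16. At an unadjusted p under 0.05, limma had 2 of the 74 higher and 42 lower. Rps25 fell from 671 ± 15.4 to 557 ± 28.1 FPKM and Rps24, on chromosome 14, from 841 ± 12.7 to 600 ± 26.2 (list camera adjusted p = 6.12e-11; adjusted p = 0.953 with an estimated correlation).

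In total 1691 of 11287 tested genes changed in the high line against control, 905 rising and 786 falling, and 328 of them had an absolute log2 fold of at least 1. The count was 1056 without high 1 and 1049 without high 2. Of the changed genes, 415 (24.5%) lie on chromosomes 3, 14, 18 and Y, which hold 10.4% of the tested genes.

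The comparison of the low line with control asks the same at the intermediate Aldh1a3 level. Il5ra, the interleukin 5 receptor alpha chain, fell from 199 ± 4.71 to 2.18 ± 0.2 FPKM, and Fkbp10, Cd34 and Galnt18 fell to 0.087 ± 0.035, 0.06 ± 0.036 and 0.227 ± 0.025. The intestinal transcription factor gene Cdx2 fell from 23.3 ± 1.12 to 1.74 ± 0.34 FPKM and Ifitm1 from 354 ± 63.4 to 30.8 ± 4.31. Slco3a1, an organic anion transporter, rose from 0.093 ± 0.021 to 9.29 ± 0.95 FPKM, Lilr4b, a leukocyte immunoglobulin-like receptor, from 10.6 ± 0.38 to 92.6 ± 8.64, and the neighbouring genes Tmem176b and Tmem176a from 27.8 ± 5.86 to 205 ± 35.9 and from 16.9 ± 4.13 to 115 ± 20.3. Wnt7a, a Wnt ligand, rose from 2.15 ± 0.92 to 17.6 ± 5.33 FPKM and Cldn3 from 3.83 ± 0.93 to 25.2 ± 2.66. The log2 folds were -5.98 ± 0.13 for Il5ra, -3.15 ± 0.11 for Cdx2, 3.23 ± 0.08 for Slco3a1 and 3.01 ± 0.11 for Lilr4b, and the highest adjusted p among these genes was that of Wnt7a, 0.000293. Ccdc120, Gdpd5 and Ccbe1 also rose, by 2.37, 2.35 and 2.62, the last of these on chromosome 18, whose genes had a median of 0.40 in the low line. Col3a1, Stmn2 and the cadherin gene Cdh9 fell by 3.96, 3.39 and 3.32, as did Mgp, a matrix calcification inhibitor, by 4.39 from a control level of 38.8 ± 38.9 FPKM whose SD matches its mean.

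Retinoic acid receptors and targets rose more often than they fell in the low line, Cyp26b1 and Stra6 also being on the list of retinoid metabolism. Cyp26b1 rose from 2.76 ± 0.36 to 14.7 ± 2.22 FPKM, Stra6, the cellular importer of retinol, from 0.033 ± 0.042 to 2.12 ± 0.36, and Hoxa3, a retinoic acid-responsive homeobox gene, from 0.31 ± 0.15 to 1.83 ± 0.2. The retinol dehydrogenase gene Rdh10 rose from 64.3 ± 3.29 to 92 ± 4.77 FPKM. Among 16 tested receptors and targets, 6 rose, 1 fell and 9 did not pass, or 7 and 1 adjusted over the list alone, with a median of 0.23. Its camera adjusted p = 0.0183 became 0.0526 without control 2, 0.11 without control 3 and 0.0692 without the libraries numbered 3, and adjusted p = 0.857 with an estimated correlation. The median of this list became 0.145 without control 2 and 0.127 without control 3. In retinoid metabolism 4 of 13 rose and 2 fell, or 4 and 3 adjusted over the list alone (camera adjusted p = 0.216; adjusted p = 0.857 with an estimated correlation). Of 15 other aldehyde dehydrogenases 1 rose and 4 fell, with the same counts adjusted over the list alone: Aldh7a1, on chromosome 18, rose from 14.2 ± 0.61 to 24.9 ± 0.84 FPKM and Aldh1l1 fell from 6.78 ± 0.82 to 1.34 ± 0.21 (camera adjusted p = 0.215; adjusted p = 0.857 with an estimated correlation).

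Guidance genes beyond the semaphorins fell more often than they rose in the low line, with 8 falling, 2 rising and 10 not passing of 20 tested, or 9 and 4 adjusted over the list alone, and a median of -0.37. The repellent ligand gene Slit3 fell from 2.36 ± 0.87 to 0.267 ± 0.07 FPKM, the netrin receptor gene Unc5c from 4.87 ± 0.19 to 1.42 ± 0.16 and Ephb6 from 15.4 ± 6.53 to 5.23 ± 1.12, while the netrin gene Ntn1 rose from 2.22 ± 0.6 to 14 ± 2.11. Camera gave adjusted p = 0.00437, and adjusted p = 0.857 with an estimated correlation. Semaphorins included 1 that rose and 3 that fell of 14 tested, with the same counts adjusted over the list alone, Sema6d falling from 4.64 ± 0.32 to 2.39 ± 0.33 FPKM (camera adjusted p = 0.216; adjusted p = 0.956 with an estimated correlation). Of 9 plexins and neuropilins 2 rose and 0 fell, with the same counts over the list alone (camera adjusted p = 0.0704; adjusted p = 0.857 with an estimated correlation). Mesenchymal genes also fell more often than they rose, 11 falling, 2 rising and 12 not passing of 25, or 14 and 3 adjusted over the list alone, with a median of -0.31. Col5a2, a fibrillar collagen gene, fell from 5.83 ± 0.65 to 0.023 ± 0.015 FPKM and Acta2, the smooth muscle actin gene, from 12.3 ± 5.05 to 1.01 ± 0.41 (list camera adjusted p = 0.000232; adjusted p = 0.857 with an estimated correlation). Of the 4 fibroblast markers 3 fell and 0 rose, with the same counts adjusted over the list alone and a median of -2.54.

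Of 23 glycolysis genes 7 fell, 3 rose and 13 did not pass, or 12 and 3 adjusted over the list alone, with a median of -0.32 (camera adjusted p = 0.00437, 0.108 under quantile normalization; adjusted p = 0.857 with an estimated correlation). Against that direction, the regulator Pfkfb4 rose from 2.42 ± 0.15 to 7.56 ± 0.25 FPKM and Ldhb from 0.733 ± 0.049 to 2.73 ± 0.63. Of these 23 genes, 15 were lower in the libraries numbered 3 than in those numbered 1, as were 10 of 20 targets of NF-kB, with 3 of these higher. Among 20 targets of NF-kB 4 rose, 1 fell and 15 did not pass, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.0125; adjusted p = 0.857 with an estimated correlation). Tnfaip3, a feedback inhibitor, rose from 3.54 ± 0.71 to 12.9 ± 3.86 and the adhesion gene Vcam1 fell from 19.7 ± 7.05 to 4.4 ± 1.85 FPKM. Wnt targets rose in 6 and fell in 1 of 10 tested, with the same counts adjusted over the list alone. Axin2, a feedback inhibitor of Wnt signalling, rose from 0.863 ± 0.29 to 3.11 ± 0.24 FPKM and Apcdd1, a Wnt inhibitor on chromosome 18, fell from 14.6 ± 3.1 to 2.51 ± 0.28. Its camera adjusted p = 0.0229 became 0.0823 without control 2, 0.0513 without control 3 and 0.0604 without the libraries numbered 3, and adjusted p = 0.857 with an estimated correlation. Targets of YAP rose in 6 and fell in 1 of 22, or 11 and 3 adjusted over the list alone, with Ankrd1 rising from 46.9 ± 7.61 to 133 ± 33.2 and Ccn2 from 42 ± 3.49 to 89.6 ± 13.6 FPKM. This call (camera adjusted p = 0.0229) became 0.0513 without control 3 and 0.0924 without low 1, and adjusted p = 0.857 with an estimated correlation. With the filter at 5 FPKM the camera adjusted p in the low line became 0.36 for retinoic acid receptors and targets, 0.444 for guidance genes, 0.485 for Wnt targets and 0.0799 for YAP targets. Their medians were then 0.08, -0.13, 0.17 and 0.21, against 0.23, -0.37, 0.37 and 0.23 in the main fit.

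In the low line 1353 of 11287 genes changed against control, 684 rising and 669 falling, 306 of them by an absolute log2 fold of at least 1. With the library number as a block, the count was 2590, and all 1353 were among them. The block gave 3 rising and 16 falling genes of glycolysis, 11 and 1 targets of NF-kB, and 11 and 5 targets of YAP. Chromosomes 3, 14, 18 and Y hold 262 (19.4%) of the changed genes.

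The high and the low line were compared directly, with no control library in the contrast. Il5ra was higher in the high line, 44.9 ± 9.54 against 2.18 ± 0.2 FPKM, as were Pcdh10, a protocadherin gene on chromosome 3 (15.3 ± 2.57 against 0.71 ± 0.25), Epas1, which encodes a hypoxia-inducible factor (13.3 ± 4.11 against 0.863 ± 0.31), the keratin gene Krt20 (6.17 ± 0.49 against 0.223 ± 0.051) and the interleukin 1 receptor antagonist gene Il1rn (16.3 ± 1.05 against 2.53 ± 0.99). Lower in the high line were Ifitm1 (0.757 ± 0.32 against 30.8 ± 4.31 FPKM), Slco3a1 (0.01 ± 0.01 against 9.29 ± 0.95), the chemokine gene Ccl2 (0.02 ± 0.017 against 7.84 ± 3.84) and Crabp1 (0.15 ± 0.062 against 8.39 ± 2.94). Their log2 folds were 3.83 for Il5ra, 3.26 for Pcdh10, 2.91 for Epas1, 2.55 for Krt20, 2.33 for Il1rn, -4.19 for Ifitm1, -3.34 for Slco3a1, -3.03 for Ccl2 and -2.99 for Crabp1, with adjusted p up to 0.000578 (Ccl2). Prl2c2, a placental proliferin gene, also fell by 3.55 (adjusted p = 0.00518), but near-identical family members make its assignment uncertain.

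Retinoid genes separated the lines in both directions. Aldh1a1 was higher in the high line (2.66 ± 0.78 against 0.26 ± 0.16 FPKM), while Stra6 (0.243 ± 0.11 against 2.12 ± 0.36), Hoxa3 (0.147 ± 0.035 against 1.83 ± 0.2) and Crabp2 (1.4 ± 0.55 against 6.81 ± 0.24) were lower. Of 13 tested genes of retinoid metabolism 3 rose and 5 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.174; adjusted p = 0.833 with an estimated correlation), and of 16 receptors and targets 4 rose and 4 fell, or 4 and 5 adjusted over the list alone (camera adjusted p = 0.414; adjusted p = 0.886 with an estimated correlation). Guidance genes beyond the semaphorins rose more often than they fell: 8 of 20 rose, 1 fell and 11 did not pass, or 10 and 2 adjusted over the list alone, with a median of 0.34, among them Slit3 (3.99 ± 0.65 against 0.267 ± 0.07 FPKM) and Unc5c (on chromosome 3, 4.12 ± 0.61 against 1.42 ± 0.16). Camera gave adjusted p = 0.0066, and adjusted p = 0.721 with an estimated correlation. Semaphorins rose in 4 and fell in 0 of 14, or 6 and 0 adjusted over the list alone (camera adjusted p = 0.078; adjusted p = 0.833 with an estimated correlation).

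Interferon response genes fell more often than they rose: of 27 tested 8 fell, 0 rose and 19 did not pass, or 10 fell adjusted over the list alone, with a median of -0.34. Oas1a, which senses double-stranded RNA, was at 0.267 ± 0.12 against 1.84 ± 0.82 FPKM, the chemokine gene Cxcl10 at 0.377 ± 0.16 against 1.7 ± 0.17 and the tetherin gene Bst2 at 42.3 ± 1.31 against 74.2 ± 10.9. Camera gave adjusted p = 0.0066 for this list, and adjusted p = 0.833 with an estimated correlation. Across the groups, 18 of the 27 genes were lower and 0 higher in the libraries numbered 3 than in those numbered 1. Lysosomal genes rose in 5 and fell in 1 of 30, with the same counts adjusted over the list alone, the hexosaminidase gene Hexb standing at 40.5 ± 1.88 against 28.1 ± 2.48 FPKM (camera adjusted p = 0.0066; adjusted p = 0.833 with an estimated correlation). Heat shock genes fell in 4 and rose in 0 of 15, with the same counts adjusted over the list alone, Cryab, a small heat shock protein gene, most of all, at 20.6 ± 3.69 against 80.9 ± 2.24 FPKM (camera adjusted p = 0.0136; adjusted p = 0.833 with an estimated correlation). Matrix remodelling genes fell in 7 and rose in 2 of 32, or 11 and 3 adjusted over the list alone, the gelatinase gene Mmp2 standing at 0.52 ± 0.066 against 6.51 ± 1.12 FPKM. Its camera adjusted p = 0.0287 became 0.0508 without high 3, 0.107 without low 1, 0.0524 without low 2, 0.0532 with no filter and 0.0894 without the genes on chromosomes 3, 14, 18 and Y, and adjusted p = 0.833 with an estimated correlation.

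Between the lines 1785 of 11287 genes changed, 945 higher and 840 lower in the high line, 263 by an absolute log2 fold of at least 1. With the library number as a block the count was 3643, with all 1785 among them. The block gave 11 rising and 3 falling guidance genes, 7 and 1 semaphorins, 1 and 15 interferon response genes, 12 and 3 lysosomal genes and 5 and 14 genes of matrix remodelling. The count was 1065 without high 1, 1041 without high 2 and 1019 with the genes on chromosomes 3, 14, 18 and Y left out. Those chromosomes hold 581 (32.6%) of the changed genes. With the filter at 5 FPKM the camera adjusted p became 0.24 for guidance genes and 0.0577 for each of interferon response and matrix remodelling. Their medians were then 0.18, -0.18 and -0.22, against 0.34, -0.34 and -0.22 in the main fit.

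Changes shared by both overexpressing lines were counted next. Against control, 589 genes changed the same way in both lines, 284 rising and 305 falling, and 61 changed in opposite directions. Plxnb1, Cldn3, Cyp26b1, Elf3, Dclk1 and Ccn2 were among those rising in both, and Sema3a, Ifitm1, Fkbp10, Cd34, Galnt18, Col3a1 and Cdx2 among those falling in both. Both comparisons use the same 3 control libraries. In 100 simulated pairs of unchanged groups sharing these controls, 0 genes were called the same way in any draw, and independent lists of these sizes would share 54.8 rising and 46.6 falling genes. The simulation leaves out the effects and the independent lists leave out the shared controls, so neither sets the level from which a shared effect could be read, and part of the overlap can come from the controls. The log2 folds of the lines correlated across genes at r = 0.556, while the simulated pairs gave a mean of 0.448 and up to 0.988. The covariance of the folds was 0.0857, with a simulated mean of 0.0111 and a highest simulated value of 0.0914. Each simulated library took a random mixture of the observed deviations, including those that real libraries of the same number share across groups. The simulated range therefore does not come from the shared controls alone. Of the 589 genes, 421 were not called between the lines, 94 lay further from control in the high line and 74 in the low line. Genes called in the high line only and called between the lines numbered 639, and those called in the low line only and between the lines 475. The F test over all 3 groups called 2486 genes.

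**Figure D2:**
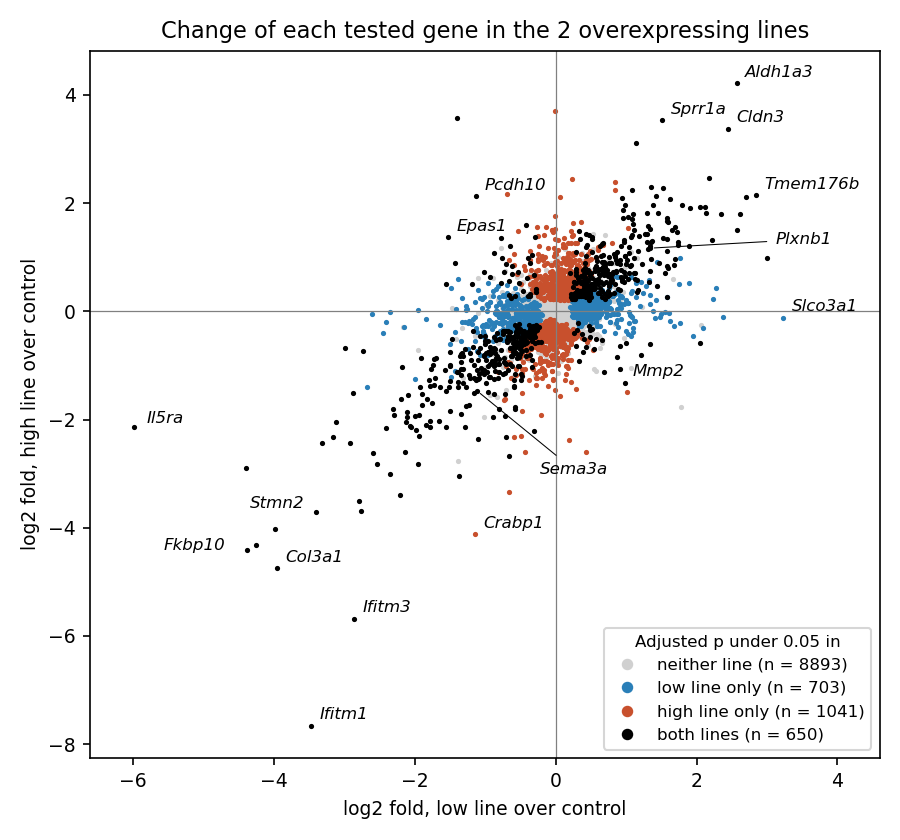
Log2 fold over control of each of the 11287 tested genes in the low line (horizontal axis) and the high line (vertical axis), on the log2(FPKM + 1) scale, coloured by the comparisons in which limma's adjusted p is under 0.05. Genes falling in both lines such as Fkbp10 and Col3a1 lie at the lower left, and Aldh1a3 and Cldn3 at the upper right.

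Whole chromosomes differed between the lines. In the high line chromosome 14 had a median log2 fold of -0.37 against control, with 189 of its 368 tested genes falling and 5 rising (adjusted p = 6.73e-05 by camera with an estimated correlation), and 92.7% of its genes lay below 0. Chromosome 3 had a median of 0.24 in the high line, with 167 of 530 genes rising and 15 falling (adjusted p = 0.00184). In the low line chromosome 18 had a median of 0.40, with 150 of 273 genes rising and 9 falling (adjusted p = 0.000869). On chromosome Y all 4 tested genes, Ddx3y, Eif2s3y, Kdm5d and Uty (named after their values were seen), rose in the high line, with a median of 0.65, and were too few to test as a set. The shifts ran along the length of each chromosome, in windows of 40 genes with a mean of at least 5 FPKM. In the high line the window medians of chromosome 14 lay between -0.44 and -0.34 and those of chromosome 3 between 0.13 and 0.32. Those of chromosome 18 in the low line lay between 0.39 and 0.45. Between the lines the medians over all tested genes were -0.39 for chromosome 14, 0.25 for chromosome 3 and -0.40 for chromosome 18. The chromosome 3 call against control was lost with the 3 libraries numbered 3 left out (adjusted p = 0.0835). With no filter, which adds genes of low expression, the medians were -0.25 on chromosome 14 and 0.11 on chromosome 3 in the high line and 0.21 on chromosome 18 in the low line (adjusted p = 0.000787, 0.00859 and 0.00439).

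**Figure D3:**
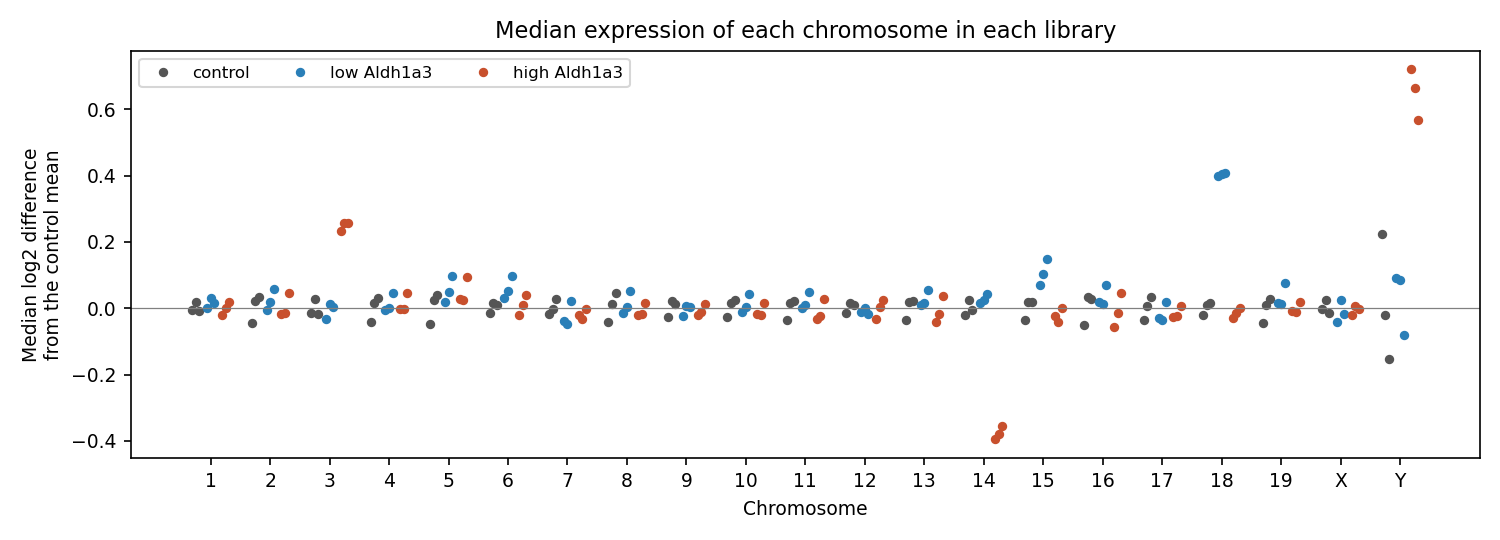
Median difference of the tested genes of each chromosome with a mean of at least 5 FPKM from the control mean. Values are in log2(FPKM + 1), for each of the 9 libraries (points, coloured by group). The high libraries lie between -0.40 and -0.36 on chromosome 14, and the low libraries between 0.40 and 0.41 on chromosome 18. The 3 genes of chromosome Y at this level scatter more.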

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

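The tests of a response growing with the Aldh1a3 level on single chromosomes, of clone selection, and of oxygen supply and growth were chosen only after the results were seen. Groups of 3 libraries are too small to test a single library as an outlier.

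Whole chromosomes differed between the overexpressing lines by the direct test: the median log2 fold, high minus low, was 0.25 on chromosome 3 (adjusted p = 0.000631), -0.39 on chromosome 14 (0.000112), and -0.40 on chromosome 18 (0.000413). Chromosome 15 passed at -0.13 (0.0447), a call lost with the block (0.144), without control 1, control 2, control 3, high 1, high 2, high 3 or low 2 (0.0598 to 0.121) and under 4 further settings (up to 0.303). Correcting for GC content, transcript length and expression left -0.37 on chromosome 14 in the high line and 0.39 on chromosome 18 in the low line, which argues against these properties as the source. A response growing with the Aldh1a3 level is argued against for chromosome 18, at -0.0182 in the high line against control; for chromosomes 14 and 3 it cannot be told apart from a difference between clones, because the low line was at 0.0174 on chromosome 14 and a response may set in only at the higher level. Different copy numbers of whole chromosomes may underlie the shifts: among 3 expression classes of chromosome 14 genes in the high line the median nearest to 0 was still -0.36, while a change in part of the genes could have left a class near 0, and as no DNA was measured this stays a hypothesis.

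Genes that changed did not line up with the Aldh1a3 level as a set. Among the 2486 genes past the F test the low line lay between control and the high line in 36%, the control in between in 36.2% and the high line in 27.8%, and with chromosomes 3, 14, 18 and Y left out the low line was in between in 37.3%. This argues against a response graded with Aldh1a3 as a description of the whole set, although parts of it may be graded. Selection of single clones may contribute: 475 genes stood apart in the low line alone, but each level comes from monoclonal selection, so clone and level cannot be told apart.

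Deviations from the group means correlated between libraries of the same number at r = 0.102 to 0.769 in 8 of 9 pairs, and at -0.0047 for control 2 with high 2. The first axis took 66.5% of these deviations, and 4684 genes differed between numbers 3 and 1 in the blocked model, 2592 of them higher and 2092 lower in number 3. The axis took 76.4% among genes of at least 20 FPKM, which argues against depth, and GC content and length accounted for 1.57% of its loadings, which argues against a bias in either. Oxygen supply and growth of the cultures may be involved, as the hypoxia list had a median of -0.60 (21 of 25 lower), with 15 of 23 glycolysis genes lower and 36 of 44 S phase genes higher in number 3. With an estimated correlation the hypoxia list gave an adjusted p = 0.531, so culture state cannot be told apart from other differences between preparations.

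Splitting the samples otherwise, 1 of 10 splits gave as many changed genes as the real one in each comparison of a pair of groups, which is the real split itself. The real counts and the highest of the other splits were 1691 and 716 for high against control, 1353 and 1 for low against control, and 1785 and 0 for high against low. With 10 splits no share under 0.05 is possible. The split with 716 genes set control 1, high 1 and high 2 (-24.07, -9.11 and -6.71 on the first axis of the deviations) against control 2, control 3 and high 3 (4.93, 19.14 and 15.81). It thus parts the libraries by the sign of that axis. In both groups it sets number 1 against number 3, and it divides number 2. For genes changed in any group, 1 of 100 splits drawn from 280, the real one, gave as many as 2486. The highest other gave 1418, so a random division of these libraries is unlikely to reach the real count. The splits treat libraries as independent, which the labels do not settle, so differences between clones or cultures are not excluded.

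Given here are 6 named genes called in opposite directions in the lines against control and also called between the lines. Their selection used the direct test, and each difference follows from the folds against control. Its adjusted p is therefore no separate support. The log2 fold, high minus low, was -2.30 for Mmp2 (-1.32 in the high and 0.98 in the low line), -1.94 for Cryab (-0.59 and 1.35) and -0.83 for Rdh10 (-0.32 and 0.51). It was 3.26 for Pcdh10 (2.13 and -1.13), 2.91 for Epas1 (1.38 and -1.53) and 1.05 for Aldh1a2 (0.53 and -0.52), with adjusted p of the difference from 1.55e-05 (Pcdh10) to 0.00131 (Aldh1a2). Both calls of Aldh1a2 against control were near the threshold (limma adjusted p = 0.033 in the high and 0.041 in the low line). They were not rerun under the alternatives. The fall of Cryab in the high line (adjusted p = 0.0475) was lost without any single library except control 1. The adjusted p was 0.162 without control 2, 0.138 without control 3, 0.157 without high 1, 0.0823 without high 2, 0.056 without high 3, 0.0745 without low 1, 0.0754 without low 2, 0.067 without low 3. Over all its alternatives the adjusted p lay between 0.000403 with weights per library and 0.163 without the libraries numbered 3.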

How the results depend on the processing

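The tests of whole chromosomes under other settings, camera with an estimated correlation together with the block, and the fits without the libraries numbered 3 or without the genes on chromosomes 3, 14, 18 and Y, were chosen after the data were seen; all others were planned. The directions of Aldh1a3 and of the shifts on chromosomes 14 and 18 held past the threshold under every alternative run, with the Aldh1a3 fold in the high line from 4.13 to 4.47 against control. No scaling moved the median of all genes by over 0.1.

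Weights per library, estimated from 3 libraries a group by an iteration that stopped before it converged, gave 5689, 2952, 4016 and 6426 changed genes for high against control, low against control, high against low and any group, and 1665 shared by both lines. The list of G2/M genes then had a median of -0.13 in the low line, against 0.05 without weights, and chromosome 15 between the lines -0.13 (adjusted p = 0.0571); the cause was not tested. Quantile normalization kept 24 of 29 list calls. It turned the median of ribosomal protein genes in the low line from -0.10 to 0.0007 (adjusted p = 0.993) and ended the calls of glycolysis in the low line (0.108) and between the lines (0.0838), heat shock in the high line (0.0576) and hypoxia in the low line (0.0516); the cause was not tested.

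The library number as a block gave 3384, 2590, 3643 and 4758 genes and 1193 shared, since it removes the deviations shared by number. It kept 29 of 29 list calls and all 398 calls of named genes, and left chromosome 15 at -0.13 (adjusted p = 0.144). It added camera calls for S phase (0.0355), TGF-beta targets (0.0408) and the unfolded protein response (0.0237) in the high line, and for hypoxia (0.034), ductal markers (0.0316) and MHC class I (0.0256) between the lines. With the block and an estimated correlation these had adjusted p = 0.992 in the high line and 0.827 between the lines. Deviations of control and high correlated at r = 0.662, -0.0047 and 0.734 for numbers 1, 2 and 3. Numbers 1 and 3 thus shared deviations across these groups, and number 2 did not. Of 9 libraries, 6 matched their own number best, and control 2, high 2 and low 2 did not.

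A minimum absolute log2 fold of 1 left 328, 306, 263 and 146 shared genes, by construction. The filter at 5 FPKM, with fewer genes tested, gave 878 genes in the low line, 366 shared, 7 lists in the low line and -0.15 on chromosome 15 (adjusted p = 0.0585). No filter, which adds genes of low expression, gave medians of -0.25 on chromosome 14 and 0.11 on chromosome 3 in the high line and 0.21 on chromosome 18 in the low line. Between the lines it gave -0.23, 0.14 and -0.23 on these and -0.05 on chromosome 15. Of 8, 11 and 10 lists called by camera, an estimated correlation kept 0, 0 and 0, with or without the block. Without the block, 1, 2 and 2 of all 40 lists had an unadjusted p under 0.05 by that test. Fry kept 9 of the 29 camera calls and lost 20. Among all 40 lists it called 4, 9 and 5 in the 3 comparisons. Fitting only the groups compared left chromosome 15 at -0.13 (adjusted p = 0.148), with fewer samples. Without the libraries numbered 3, chromosome 3 in the high line was at 0.24 (adjusted p = 0.0835) and chromosome 15 at -0.12 (0.303), with 2 libraries a group. Without chromosomes 3, 14, 18 and Y, 1019 genes changed between the lines.

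Leaving out each library gave 1049 to 2044 genes for high against control, 906 to 1313 for low against control, 1041 to 2286 for high against low, 1721 to 2911 for any group and 418 to 624 shared. It gave 6 to 12 lists between the lines and -0.14 to -0.12 on chromosome 15. That call was lost without control 1, control 2, control 3, high 1, high 2, high 3 or low 2 (adjusted p = 0.0838, 0.0598, 0.086, 0.0661, 0.0768, 0.121 and 0.0899), and over all its alternatives its adjusted p lay between 0.00148 and 0.303. Without high 1, 6 lists were called between the lines. Of 398 calls of named genes, leaving out a single library kept between 314 (high 2) and 380 (control 1). If the step in the smallest values is 1 fragment, 1 FPKM of a transcript of 1 kilobase rests on 36.6 to 64.1 fragments, so values near 0.02 FPKM rest on about 1.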

Other observations

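The tests of lists in this part were planned. The fits without the libraries numbered 3, and the block with an estimated correlation, were chosen only after the data were seen. So were the counts between numbers 3 and 1 and the count of genes off in both lines. Genes of antigen presentation by MHC class I rose in 5 and fell in 1 of 18 tested in the high line against control, with the same counts adjusted over the list alone (camera adjusted p = 0.424; adjusted p = 0.953 with an estimated correlation). Nlrc5, the transactivator of MHC class I genes, rose from 0.163 ± 0.045 to 1.35 ± 0.061 FPKM, H2-Q4 from 5.6 ± 0.91 to 12.7 ± 0.63 and B2m, the shared light chain, from 250 ± 34.4 to 392 ± 13.7. Across the groups, 9 of the 18 genes were lower and 1 higher in the libraries numbered 3 than in those numbered 1. Chemokines and cytokines rose in 2 and fell in 5 of 23 in the high line, with the same counts adjusted over the list alone (camera adjusted p = 0.724; adjusted p = 0.953 with an estimated correlation). Cxcl12 rose from 25.5 ± 4.58 to 73.7 ± 13.6 FPKM and Vegfc, a lymphatic growth factor, fell from 2.22 ± 0.23 to 0.237 ± 0.021. In the low line 4 of them rose and 1 fell, 6 and 1 adjusted over the list alone, or 9 and 2 with the block (camera adjusted p = 0.184; adjusted p = 0.857 with an estimated correlation). Il1a rose there from 0.14 ± 0.02 to 3.33 ± 1.12 FPKM and Il1rn fell from 16.5 ± 1.41 to 2.53 ± 0.99. Drug transport genes rose in 4 and fell in 2 of 13 in the high line, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.151; adjusted p = 0.953 with an estimated correlation). The efflux pump gene Abcb1a rose from 3.79 ± 0.73 to 8.1 ± 0.95 FPKM and Abcg2 fell from 8.27 ± 0.87 to 4.88 ± 0.91. Integrins rose in 4 and fell in 3 of 13 in the high line, or 6 and 3 adjusted over the list alone (camera adjusted p = 0.424; adjusted p = 0.953 with an estimated correlation), where Itgb7 fell from 6.43 ± 2.66 to 0.89 ± 0.19 FPKM. Of the 13 integrins 8 were lower and 1 higher in the libraries numbered 3 than in those numbered 1. In the low line Itgb2, the leukocyte beta chain, rose from 1.62 ± 0.21 to 11.3 ± 1.51 FPKM.

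Genes linked to stemness rose in 3 and fell in 1 of 17 in the low line, 3 and 2 adjusted over the list alone, or 4 and 3 with the block (camera adjusted p = 0.534; adjusted p = 0.861 with an estimated correlation). The intermediate filament gene Nes, on chromosome 3, rose from 18.2 ± 1.52 to 46 ± 8.06 FPKM. Genes of the classical pancreatic cancer subtype rose in 4 and fell in 2 of 14 in the low line, with the same counts adjusted over the list alone (camera adjusted p = 0.501; adjusted p = 0.956 with an estimated correlation). Gata6, on chromosome 18, rose from 0.647 ± 0.12 to 2.06 ± 0.43 FPKM. In the high line 3 rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.935; adjusted p = 0.965 with an estimated correlation), and Foxa2 fell from 10.4 ± 0.28 to 5.31 ± 0.11 FPKM. Of 44 S phase genes limma called 0 in the high line against control, with 0 at an unadjusted p under 0.05, though 4 lay above 0 and the median was -0.16 (camera p = 0.0375, adjusted p = 0.125; adjusted p = 0.965 with an estimated correlation). With the block, whose number 2 did not correlate between control and high (r = -0.0047), the camera adjusted p was 0.0355, and 0.992 with an estimated correlation. Of these 44 genes 36 were higher and 0 lower in the libraries numbered 3 than in those numbered 1. Of 25 genes of the unfolded protein response limma called 0 in the high and 0 in the low line, and with the block 2 rose and 2 fell in the low line. At an unadjusted p under 0.05, 3 were lower in the high line and 0 in the low line. The medians were -0.11 and -0.06 (camera adjusted p = 0.0919 and 0.672; adjusted p = 0.953 and 0.956 with an estimated correlation). With the block the list had a camera adjusted p = 0.0237 in the high line, and 0.992 with an estimated correlation. Few markers of other cell types passed the filter: 2 of 22 immune, 2 of 12 endothelial, 4 of 14 fibroblast and 2 of 26 acinar or islet markers. The fibroblast markers Col3a1 and Pdgfrb fell in both lines, the endothelial marker Plvap rose in both, and the endothelial marker Egfl7 fell in the low line. Both tested acinar or islet markers, Prss2 and Isl1, fell in both lines, from 1.7 ± 0.42 and 1.5 ± 0.54 FPKM. The immune marker Cd68 fell in the low line (adjusted p = 0.0382), a call lost without control 1 (0.0934), control 2 (0.1), control 3 (0.0624), high 1 (0.0582), low 1 (0.138) or low 3 (0.115). Genes with at least 5 FPKM in control and under 0.5 FPKM in each library of both lines were 4: Galnt18, Fkbp10, Cd34 and Maoa, the last named after its values were seen. Near Ifitm1 and Ifitm3 on chromosome 7, Ifitm2, also named after its values were seen, was at 574 ± 51.1 FPKM in control, 260 ± 42.8 in the high line and 409 ± 35 in the low line.

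Further lists passed camera at the preset correlation, and those named here lost that call without single libraries, except ribosomal proteins in the low line. Many of these lists moved with the library number: higher in number 3 than in number 1 were 22 of 52 genes of oxidative phosphorylation, 13 of 24 of cholesterol synthesis (1 lower) and 7 of 15 heat shock genes (2 lower). Of all 11287 tested genes 2592 were higher, a share that the ribosomal proteins, at 14 of 74, did not exceed. Lower were 18 of 27 interferon response genes, 7 of 9 basal or squamous genes, 21 of 25 hypoxia genes and 12 of 25 TGF-beta targets (2 higher), against 2092 of all tested genes. In each comparison camera with an estimated correlation called 0 lists, with 1 of 40 at an unadjusted p under 0.05 in high against control, 2 in low against control and 2 in high against low. Fry called 4, 9 and 5, which kept 9 of the 29 camera calls and lost 20. Lost were all calls of matrix remodelling, glycolysis, interferon response, heat shock, lysosomal genes and NF-kB targets. The 9 further fry calls were on lists that camera at 0.01 did not call. Among them was retinoid metabolism, in the low line (fry adjusted p = 0.00669) and between the lines (0.00791). Adjusted p with an estimated correlation was 0.953 for each of the next 4 lists, in the high line. Cholesterol synthesis had 1 rising and 3 falling of 24, the same over the list alone (adjusted p = 0.0208). It became 0.0542 without control 2, 0.161 without control 3, 0.115 without high 1 and 0.138 without the libraries numbered 3. Heat shock had 0 and 4 of 15, the same over the list alone (0.0321). It became 0.129 without control 2, 0.0972 without control 3, 0.0743 without high 1, 0.0682 without the libraries numbered 3 and 0.0576 under quantile normalization. Interferon response had 0 and 4 of 27, or 1 and 5 over the list alone (0.0338). It became 0.501 without control 1, 0.12 without high 3, 0.296 with weights per library and 0.644 with the filter at 5 FPKM, where the median went from -0.24 to -0.007. Nuclear oxidative phosphorylation had 2 and 0 of 52, or 0 and 0 over the list alone (0.0338). It became 0.335 without control 1, 0.0938 without high 2, 0.0667 without high 3 and 0.0552 with weights per library.

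In the low line oxidative phosphorylation had 2 rising and 0 falling of 52, the same over the list alone, and 8 and 0 with the block (camera adjusted p = 0.0183; adjusted p = 0.956 with an estimated correlation). It became 0.17 without control 1, 0.408 without low 3, 0.188 with weights per library and 0.0823 without the libraries numbered 3. Basal or squamous genes had 1 and 2 of 9, 1 and 4 over the list alone, or 1 and 5 with the block (camera adjusted p = 0.0183; adjusted p = 0.857 with an estimated correlation). They became 0.0576 without control 1, 0.0702 without low 3, 0.0605 without the libraries numbered 3, 0.0954 with weights per library and 0.825 with no filter, where the median went from -0.20 to -0.001. Hypoxia had 2 and 2 of 25, 2 and 3 over the list alone, or 2 and 12 with the block (camera adjusted p = 0.0317; adjusted p = 0.956 with an estimated correlation). It became 0.454 without control 1, 0.47 without low 3, 0.0516 under quantile normalization, 0.0513 with median-ratio scaling, 0.0533 with no filter and 0.398 with weights per library. Ribosomal protein genes had 2 and 1 of 74, 2 and 0 over the list alone, or 2 and 9 with the block (camera adjusted p = 4.45e-05; adjusted p = 0.857 with an estimated correlation). They kept the call when each library was left out in turn, and their median turned to 0.0007 under quantile normalization (adjusted p = 0.993).

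Between the lines adjusted p with an estimated correlation was 0.886 for S phase and 0.833 for each of the other lists here. Glycolysis had 4 higher and 1 lower of 23, 7 and 1 over the list alone, or 12 and 1 with the block (camera adjusted p = 0.0105). It became 0.0605 without high 1, 0.0664 without low 3 and 0.0838 under quantile normalization. Ribosomal proteins had 2 and 6 of 74, 2 and 5 over the list alone, or 3 and 12 with the block (0.0193). They became 0.0922 without high 1, 0.244 without low 3, 0.141 with weights per library and 0.131 without the libraries numbered 3. S phase had 0 and 1 of 44, the same over the list alone, and 0 and 4 with the block (0.0278). It became 0.106 without high 1, 0.167 without high 2 and 0.206 without low 3. TGF-beta targets had 4 and 1 of 25, the same over the list alone, and 11 and 2 with the block (0.0287). They became 0.0922 without high 1, 0.055 without low 2 and 0.0664 without low 3. Cholesterol synthesis had 1 and 3 of 24, the same over the list alone, and 1 and 10 with the block (0.0374). It became 0.155 without high 1, 0.114 without low 2, 0.0541 without low 3 and 0.0559 with the filter at 5 FPKM.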
